A study of Gallus gallus with 4 samples.

How the data were processed

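The labels say that total RNA was taken from the trachea of chickens 42 days old and that sequencing libraries were made by standard Illumina protocols. Chickens of the exposed group lived in a chamber whose air held hydrogen sulfide at 3.5 to 4.5 mg/kg in weeks 0 to 3 and at 19.5 to 20.5 mg/kg in weeks 4 to 6. The control chamber received none. The groups lived in separate chambers, so the gas and other differences between the chambers cannot be told apart. Each group has 2 libraries. The labels do not say whether a library came from a single bird or from several, or whether the libraries of a group came from separate birds. Every p-value of a single gene below therefore measures only the spread between these libraries. The libraries of each group differed in genes of the sex chromosomes. Over 629 genes on the Z chromosome, the median log2 deviation from the gene's mean was -0.247 and 0.296 in the exposed libraries. In the controls it was 0.286 and -0.296. This argues against the same birds in both libraries of a group, but the number of birds stays unknown.

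The values analysed are the read counts per gene that the authors deposited, in a single table with 1 column per library and no normalization. The submitters' processing notes name HISAT2, a read aligner, without a version. The counting program, the genome build, the annotation and the use of strand are not given in the sources used here. The table lists 26296 genes by symbol with a gene type, of which 19087 are typed mRNA and 5763 lncRNA, and 4311 genes have no read in any library. Genes of the mitochondrial genome and ribosomal RNA genes are listed at 0 in all 4 libraries, so nothing can be said of them. Reads of multigene families could have been split or dropped by the counting step, so immunoglobulin, major histocompatibility complex and heat shock gene values are uncertain. Those of overlapping and antisense genes are uncertain as well. No coordinates are given, because the build behind the counts is unknown. A RefSeq gene table of assembly GRCg7b was used for names and for which genes lie on the W and Z chromosomes, and 17548 of the 26296 gene names were found in it.

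The total count was 22283320 and 22706119 reads in hydrogen sulfide replicates 1 and 2, and 17400644 and 16899066 reads in control replicates 1 and 2. Counts of any pair of libraries differed by far more than sampling noise, with a chi-square per degree of freedom from 69.3 to 121, so no library is a copy of another. The common biological coefficient of variation was 33.1%.

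The groups were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest with the current rather than the legacy dispersion method). Counts were filtered with filterByExpr by group and normalized by TMM. The test was two-sided, with no covariate, 2 residual degrees of freedom and Benjamini-Hochberg adjustment over the 16545 genes that passed the filter. Log2 fold changes are exposed over control. Their standard errors were taken as the absolute log2 fold change divided by the square root of the F statistic. Levels are TMM-normalised CPM, read counts scaled to a common library size.

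A total of 33 gene lists, for cell types and tissues that a piece of trachea can hold and for stress, immune and transport functions, were written before the data were examined. Of their 1148 entries, 991 matched a gene in the table by symbol or pattern, 45 matched through the reference table and 112 found no match. The 32 lists with at least 5 tested members were tested with camera in limma 3.58.1 on voom log2 CPM, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera sets the members of a list against all other tested genes. With the preset correlation its p-values thus rest mainly on the spread among genes, not on that between libraries or birds. The list of mitochondrial genome genes had no tested member. A list score is the mean over members of the log2 CPM, with a prior count of 2, after subtracting each gene's mean over the 4 libraries. Within each list, the edgeR p-values were also adjusted over the list alone.

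The rule for the genes named in the text was also fixed before the data were examined. It takes, among genes with an adjusted p under 0.05, a symbol that is not a bare locus or clone identifier, a mean of at least 5 CPM and no overlap between groups, the 10 largest increases and decreases. It adds 3 members of each list, or the member with the smallest p where none passed, the 3 most abundant genes that passed in each direction, and FOS, IL8L1 and IL8L2. No gene passed in the edgeR fit, so the same rule was applied to the DESeq2 1.42.0 calls after the values had been seen. There, symbols that start with LOC were left out of the most abundant genes too, which the rule did not ask for. Other genes named were likewise chosen after their values were seen. An item that the rule takes is not reported here.

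The tests were tried on counts simulated from the real libraries' means and depths and from edgeR's own estimate of each gene's spread, with 50 genes changed at each fold. Over 16545 genes, edgeR recovered 0% of the genes changed 2-fold, 48% of those changed 4-fold, 68% of those changed 8-fold and 94% of those changed 16-fold, with 17 false calls among 122. DESeq2 recovered 18%, 64%, 84% and 94% at the same folds, with 63 false calls among 193. These rates may not carry over to the real libraries. There CCL20 differed 25.5-fold between the groups and was not called by edgeR (edgeR adjusted p = 0.571). The absence of edgeR calls thus does not exclude large changes. With a list shifted by 0.5 on the log2 scale, camera called it in 10 of 10 draws with the preset correlation and in 0 of 10 draws with an estimated correlation. It called 2 of 310 tests of unshifted lists with the preset correlation. Each gene was drawn independently, so these list rates hold only for lists whose genes are not correlated. In the real libraries the estimated correlation ranged from -0.050 (thyroid, thymus and oesophagus markers) to 0.91 (interferon-stimulated genes). It was 0.14 for the cell cycle list and 0.31 for the B cell list. For ion and fluid transport genes it was 0.0077, below the preset 0.01. Their camera adjusted p still went from 2.80e-05 with the preset correlation to 0.469 with the estimated one. A call lost with an estimated correlation therefore does not by itself show that correlation explains the call.

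The alternatives fixed before the data were examined replaced TMM by DESeq2 size factors, upper-quartile factors or library totals, or removed the 50 most abundant genes. Others used no filter beyond 1 read, or a stricter filter (1 CPM in 2 libraries and a mean of 50 reads), took the replicate number as a block, or left out each library in turn. Other tests were DESeq2, limma-voom, the edgeR exact test, a robust prior, the legacy dispersion method, a test against a fold of 1.5, camera with an estimated correlation, fry, and lists without shared members. Thinning every library to the smallest total and a model term for W-linked reads, in edgeR and in DESeq2, were added after seeing the data. When a library is left out, the single library of its group is assumed to vary like the other group. No gene of the table was left out for a reason other than the filter on low counts.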

Results

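Gene expression was measured by RNA sequencing in the trachea of chickens 42 days old, with 2 libraries from the hydrogen sulfide chamber and 2 from the control chamber. Hydrogen sulfide is a toxic gas that builds up in poultry houses, and the series asks which genes and cell functions it altered in the airway. The deposited counts summed to 22283320 and 22706119 reads in the exposed libraries and to 17400644 and 16899066 in the controls. Of 26296 genes, 16545 had enough reads to be tested. In a principal component analysis, the first component held 42.7% of the variance and set the control libraries apart from each other, at 61.9 and -53.7. The groups were separated by the third component, with 26.9% of the variance, at 39.7 and 24.3 for the exposed libraries and -27.5 and -36.5 for the controls.

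Markers of B cells and plasma cells and genes of the cell cycle were lower in the exposed tracheas. Of 22 B cell and plasma cell markers, 21 had a lower level after exposure, with a median log2 fold change of -0.94. The immunoglobulin light chain gene IGLL1 stood at 1233 ± 194 CPM in the exposed group and 6462 ± 294 CPM in the control group (SD, n = 2 libraries each; log2 fold change -2.39, SE 0.41). The joining chain gene IGJ, which links secreted immunoglobulin into polymers, stood at 858 ± 138 against 5089 ± 1062 CPM (-2.57, SE 0.40). The receptor TNFRSF13B, which regulates B cell survival and class switching, had a log2 fold change of -1.94 (SE 0.27). All 40 tested cell cycle genes were lower, with a median of -0.93, and all 40 had no overlap between the groups. Of the 16545 tested genes, 2852 were lower with no overlap. The cell cycle genes are correlated with each other (estimated correlation 0.14), so this share does not weigh the 40 together. Of these 40, the mitotic kinases PLK1 and AURKA had log2 fold changes of -1.46 (SE 0.21) and -1.31 (SE 0.22). The mitotic kinesin KIF20A had -1.27 (SE 0.23). The proliferation marker MKI67 stood at 122 CPM against 227 CPM.

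As sets, the B cell list (camera adjusted p = 2.13e-19) and the cell cycle list (camera adjusted p = 1.88e-43) were lower than the other tested genes. Both calls are lost with an estimated correlation (adjusted p = 0.469 for each). In the simulation that setting called a list shifted by 0.5 in 0 of 10 draws. Its losses, here and for the lists below, therefore cannot tell whether a shift is real. Adjusted over the list alone, 15 of the 22 B cell markers and 37 of the 40 cell cycle genes passed in the edgeR fit, against 0 and 0 when adjusted over all genes tested. Both counts were 0 when either exposed library was left out. Without control replicate 1 they were 16 and 24, and without control replicate 2 they were 9 and 25. The B cell score was -0.52 and -0.49 in the exposed libraries and 0.35 and 0.66 in the controls. The cell cycle score was -0.40 and -0.54 against 0.48 and 0.46.

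**Figure D1:**
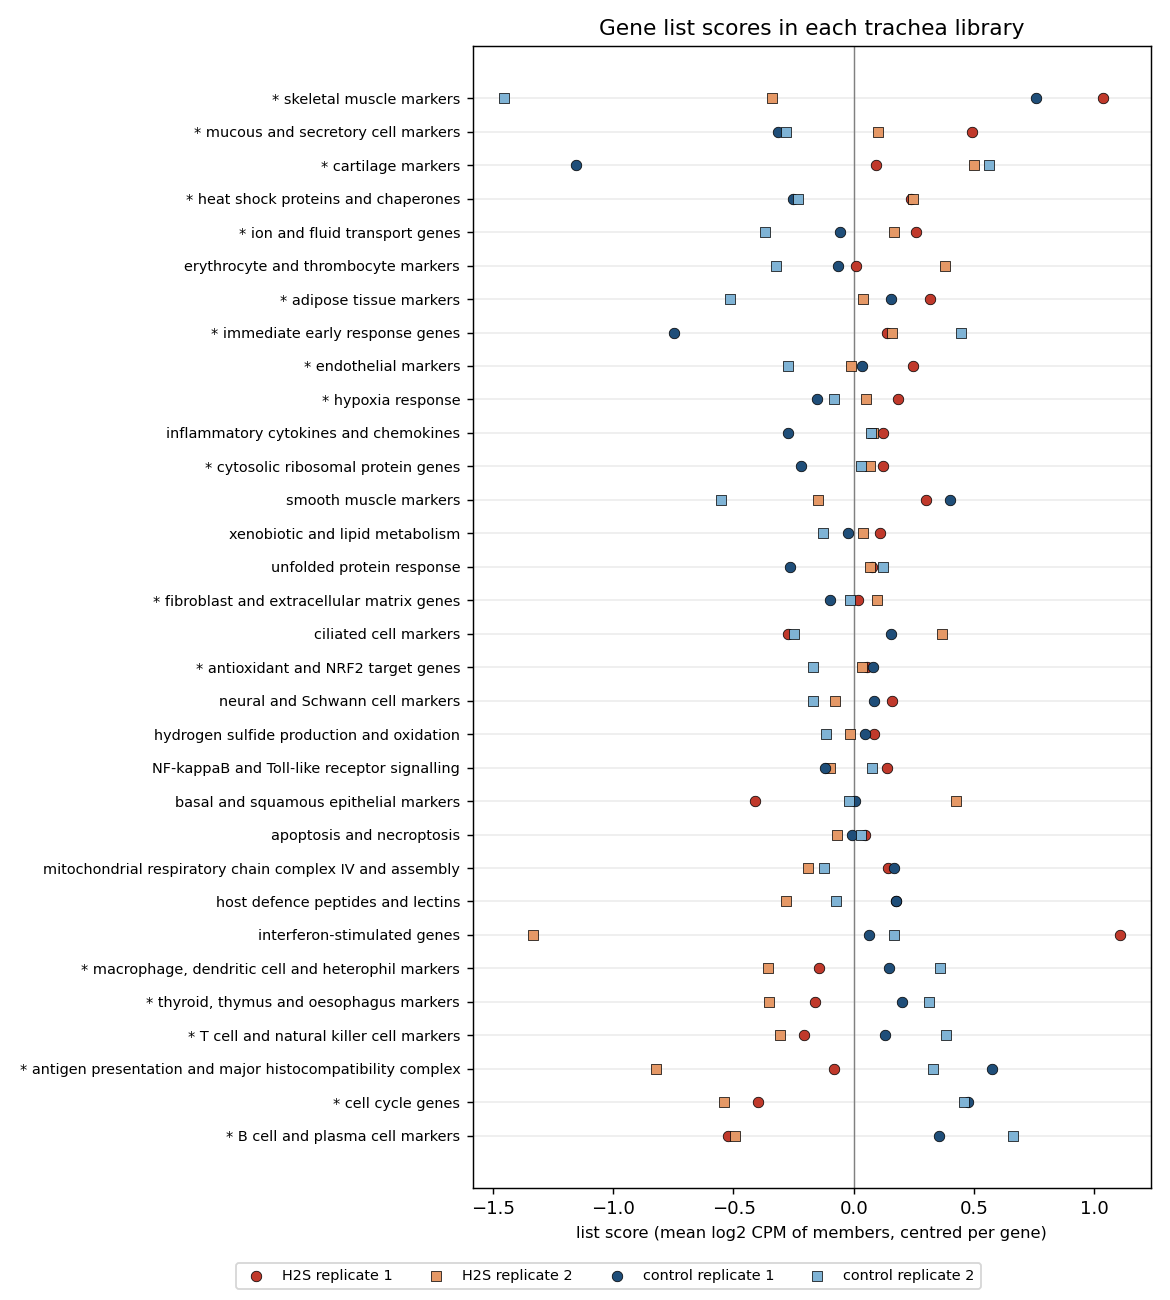
Score of each of the 32 tested gene lists (horizontal axis, mean over members of log2 CPM after subtracting each gene's mean over the 4 libraries) in each trachea library. Circles are replicate 1 and squares replicate 2, red and orange the exposed libraries and blue the controls, and an asterisk marks a list past adjusted p 0.05 by camera with the preset correlation. The cell cycle score was -0.40 and -0.54 in the exposed libraries and 0.48 and 0.46 in the controls, whereas the skeletal muscle score spread from 0.76 to -1.46 between the control libraries.

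Genes of antigen presentation and markers of other immune cells were also lower. All 19 tested genes of antigen presentation and the major histocompatibility complex had a lower level after exposure, with a median log2 fold change of -0.86 (camera adjusted p = 1.92e-14, and adjusted p = 0.482 with an estimated correlation). The class I gene BF2 stood at 316 ± 101 CPM against 1220 ± 213 CPM (SD, n = 2; log2 fold change -1.95, SE 0.33), and BF1 had a log2 fold change of -1.35 (SE 0.30). LOC101747454, which the reference table names as the class II beta chain gene BLB2, had a log2 fold change of -1.13 (SE 0.18). These are members of a polymorphic gene family, and how their reads were assigned is not given in the sources used here. Macrophage, dendritic cell and heterophil markers had a median of -0.43, with 28 of 35 lower (camera adjusted p = 3.00e-07, and adjusted p = 0.469 with an estimated correlation). They included the dendritic cell receptor FLT3 (log2 fold change -1.76, SE 0.29) and the phagocyte oxidase subunit CYBB (-1.43, SE 0.24). T cell and natural killer cell markers had a median of -0.40, with 27 of 33 lower (camera adjusted p = 3.00e-07, and adjusted p = 0.469 with an estimated correlation). Granzyme A, GZMA, stood at 2.01 ± 0.226 CPM against 10.7 ± 6.90 CPM (SD, n = 2). CD2 stood at 3.46 ± 0.0398 against 8.50 ± 0.929 CPM (SD, n = 2). XCR1, which is also in the macrophage, dendritic cell and heterophil list, stood at 1.37 ± 0.625 against 5.80 ± 0.564 CPM (SD, n = 2). These medians moved when a library was left out. That of antigen presentation was -1.31 without hydrogen sulfide replicate 1 and -0.51 without hydrogen sulfide replicate 2, and that of the macrophage list -0.65 without hydrogen sulfide replicate 1. The T cell median was -0.13 without control replicate 2 (camera adjusted p = 0.0212), -0.70 without control replicate 1 and -0.61 without hydrogen sulfide replicate 1.

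Adjusted over the list alone, 2 genes of antigen presentation, 5 macrophage, dendritic cell and heterophil markers and 0 T cell markers passed in the edgeR fit. None of these passed when adjusted over all genes tested. The 5 became 0 when any one of the 4 libraries was left out. The 2 genes of antigen presentation became 10 without hydrogen sulfide replicate 1, 0 without hydrogen sulfide replicate 2, 3 without control replicate 1 and 4 without control replicate 2. The antigen presentation score was -0.083 and -0.82 in the exposed libraries against 0.58 and 0.33 in the controls.

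Mucous cell, ion transport and heat shock genes were higher in the exposed tracheas. Of 32 markers of mucous and secretory cells, 26 were higher, with a median log2 fold change of 0.45 (camera adjusted p = 2.80e-07, and adjusted p = 0.469 with an estimated correlation). The median was 0.22 without hydrogen sulfide replicate 1. The protein disulfide isomerase AGR2, needed for mucin folding, stood at 387 ± 46.4 CPM against 109 ± 31.7 CPM (SD, n = 2; log2 fold change 1.83, SE 0.27). SPDEF, a transcription factor of goblet cells, had a log2 fold change of 1.81 (SE 0.50), and LOC395381, named as the mucin gene MUC5B in the reference table, 2.43 (SE 0.41). The gene listed as MUC, which was in no list, stood at 4234 ± 1322 CPM against 1231 ± 516 CPM (1.78, SE 0.49). Ion and fluid transport genes had a median of 0.37, with 25 of 28 higher (camera adjusted p = 2.80e-05, and adjusted p = 0.469 with an estimated correlation). They shared 5 members with other lists. The anion transporter SLC26A9 had a log2 fold change of 1.09 (SE 0.24) and the calcium-activated chloride channel ANO1 0.72 (SE 0.22).

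Heat shock proteins and chaperones had a median log2 fold change of 0.35, with 29 of 33 higher (camera adjusted p = 4.61e-09, and adjusted p = 0.469 with an estimated correlation). The co-chaperone DNAJA4 stood at 206 ± 28.5 CPM against 79.3 ± 10.1 CPM (SD, n = 2; log2 fold change 1.38, SE 0.19). The small heat shock protein gene HSP25 stood at 36.2 ± 0.988 against 7.91 ± 4.01 CPM (2.19, SE 0.40). HSPA2 stood at 810 ± 208 against 361 ± 60.5 CPM (1.17, SE 0.28). The heat shock score was 0.24 and 0.25 in the exposed libraries and -0.25 and -0.23 in the controls. Adjusted over the list alone, 3 heat shock genes (DNAJA4, HSP25 and BAG3), 2 mucous cell markers (AGR2 and LOC395381) and 0 ion transport genes passed in the edgeR fit, against 0 when adjusted over all genes tested. The heat shock count was 2 without control replicate 2 and 0 without each of the other libraries. The mucous count was 1 without hydrogen sulfide replicate 1, 5 without hydrogen sulfide replicate 2, 0 without control replicate 1 and 2 without control replicate 2.

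**Figure D2:**
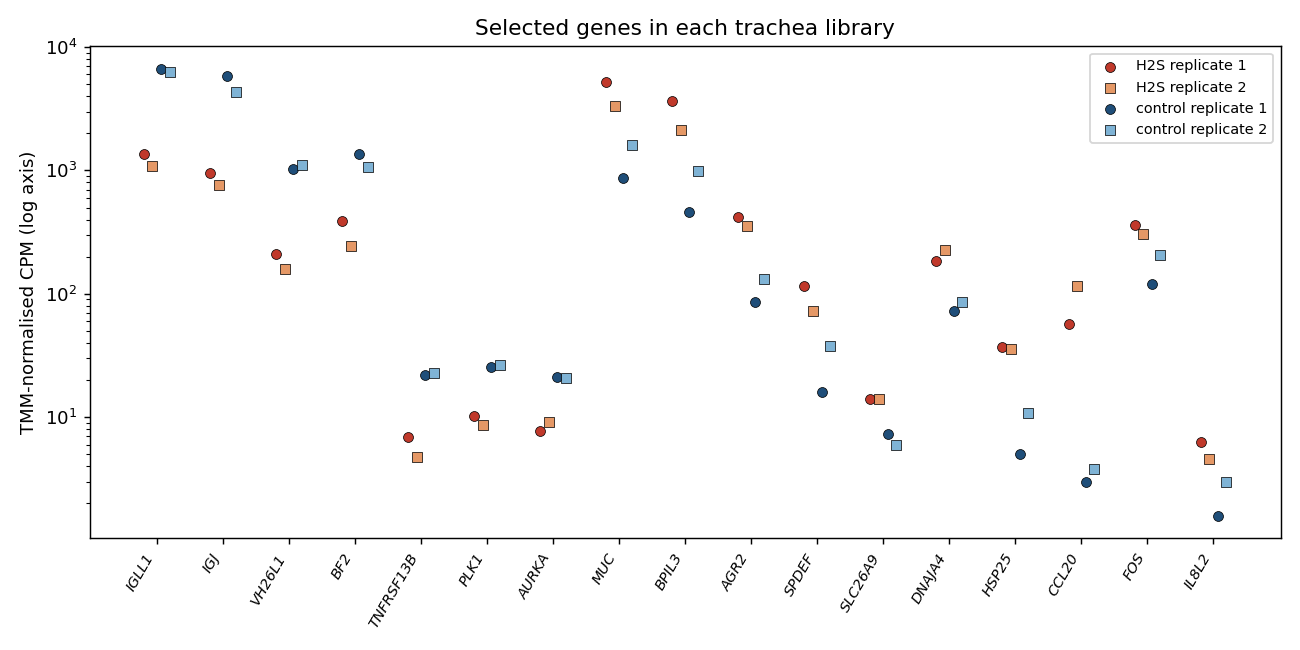
TMM-normalised CPM (log axis) of 17 genes in each trachea library, with 1 point per library, circles for replicate 1 and squares for replicate 2, red and orange for the exposed libraries and blue for the controls. IGLL1 and IGJ lie lower, and MUC, AGR2 and CCL20 higher, in both exposed libraries than in both controls, with CCL20 at 56.8 and 116 CPM against 3.00 and 3.78 CPM.

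Gene by gene, edgeR's quasi-likelihood test called 0 of the 16545 genes at an adjusted p under 0.05, with a smallest adjusted p of 0.571. In the same edgeR fit 926 genes, or 5.6% of those tested, had an unadjusted p under 0.05, 351 higher and 575 lower after exposure. Chance alone gives a share of about 0.05. DESeq2 called 132 genes, 50 higher and 82 lower, and the edgeR exact test 79, 30 higher and 49 lower. The count was 0 with limma-voom, a robust prior, the legacy dispersion method and a test against a fold of 1.5. In the simulation, whose spread came from edgeR's estimates, 63 of 193 DESeq2 calls and 17 of 122 edgeR calls were false. Both shares exceeded the 0.05 aimed at. The DESeq2 adjusted p-values are therefore likely too small, and those of edgeR may be as well. Dividing the same libraries by replicate number gave 249 DESeq2 calls and 1273 genes with an unadjusted edgeR p under 0.05. Dividing them by W-linked reads gave 70 and 723. Of the tested genes, 32.5% had no overlap between the groups, against 33.3% by chance with 2 libraries in each group. With 2 libraries against 2, an exact permutation test of a single gene cannot give a p under 0.333.

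Among the DESeq2 calls, the genes of largest change whose symbol is not a bare locus identifier were chosen after the values were seen. Of the 132 calls, 44 have a symbol that starts with LOC and were left out of this choice, some of them with larger changes than genes named here. Among the increases, the chemokine gene CCL20, whose product attracts dendritic cells and lymphocytes, stood at 86.4 ± 41.9 CPM against 3.39 ± 0.550 CPM (SD, n = 2; log2 fold change 4.67, SE 0.44; edgeR adjusted p = 0.571, DESeq2 adjusted p = 5.62e-20). The thiamine transporter SLC19A3 had a log2 fold change of 2.76 (SE 0.34), the surfactant protein gene SFTPA1 2.13 (SE 0.18) and TMC3 2.10 (SE 0.35). BPIL3, of the bactericidal and permeability-increasing protein family, had a log2 fold change of 2.01 (SE 0.53), and hemopexin, HPX, 1.89 (SE 0.40). HPS5 was among the most abundant of them, at 1987 ± 295 CPM against 872 ± 260 CPM. Among the decreases, the immunoglobulin heavy chain gene VH26L1 stood at 185 ± 38.6 CPM against 1066 ± 58.3 CPM (log2 fold change -2.53, SE 0.25; edgeR adjusted p = 0.571, DESeq2 adjusted p = 2.54e-15). The related genes VH26L8 (-2.92, SE 0.58) and VH26L10 (-2.06, SE 0.29) were lower too, and VH26L2 had 1 and 23 reads in the exposed libraries against 288 and 99 in the controls. Biliverdin reductase A, BLVRA, had a log2 fold change of -2.45 (SE 0.25), the inhibitory lymphocyte receptor LAG3 -2.18 (SE 0.34) and NAE1 -1.99 (SE 0.29). For immunoglobulin genes the values are uncertain, because reads of near-identical segments can be shared among them.

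Another 10 lists passed by camera, but each lost its call or its direction in at least 1 case when a library was left out. Skeletal muscle markers had a median log2 fold change of 0.35 (camera adjusted p = 9.50e-04, and adjusted p = 0.805 with an estimated correlation), but their score was 1.04 and -0.34 in the exposed libraries and 0.76 and -1.46 in the controls. XIRP1, their member with the smallest p, did not pass (edgeR adjusted p = 0.955). The median was -0.33 without control replicate 2 and -0.37 without hydrogen sulfide replicate 1, against 2.09 without control replicate 1 and 0.77 without hydrogen sulfide replicate 2. Cartilage markers had a median of 0.27 (camera adjusted p = 0.0174, and adjusted p = 0.805 with an estimated correlation), with scores of 0.091 and 0.50 against -1.15 and 0.56. Their median was -0.28 without control replicate 1 and -0.026 without hydrogen sulfide replicate 2, against 1.62 without control replicate 2 and 0.45 without hydrogen sulfide replicate 1. CILP, of that list, did not pass (edgeR adjusted p = 0.999). Immediate early genes had a median of 0.17 (camera adjusted p = 0.00717, and adjusted p = 0.805 with an estimated correlation), which was -0.23 without control replicate 1, 0.90 without control replicate 2 and 0.084 without hydrogen sulfide replicate 2. Adipose tissue markers had a median of 0.28 (camera adjusted p = 0.00138, and adjusted p = 0.676 with an estimated correlation), and endothelial markers 0.22 (camera adjusted p = 0.0142, and adjusted p = 0.718 with an estimated correlation). Both were lost without control replicate 2 (medians -0.082 and -0.0045, adjusted p = 0.696 for each) and without hydrogen sulfide replicate 1 (medians 0.061 and 0.019, adjusted p = 0.108 and 0.399). Their medians were 0.63 and 0.37 without control replicate 1, and 0.47 and 0.34 without hydrogen sulfide replicate 2.

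Hypoxia response genes had a median of 0.22 (camera adjusted p = 0.0252, and adjusted p = 0.469 with an estimated correlation), and EGLN3, an oxygen-sensing prolyl hydroxylase, stood at 31.1 ± 12.6 CPM against 16.3 ± 0.614 CPM. The list was lost without control replicate 1 (median 0.044, adjusted p = 0.296) and without hydrogen sulfide replicate 1 (median 0.10, adjusted p = 0.112). Cytosolic ribosomal protein genes had a median of 0.12 (camera adjusted p = 8.60e-04, and adjusted p = 0.805 with an estimated correlation), lost without control replicate 1 (median 0.020, adjusted p = 0.583). Their median was 0.27 without control replicate 2. Fibroblast and extracellular matrix genes had a median of 0.13 (camera adjusted p = 0.0402, and adjusted p = 0.676 with an estimated correlation), lost without control replicate 2 (median 0.20, adjusted p = 0.128) and without hydrogen sulfide replicate 2 (median 0.018, adjusted p = 0.739). Their median was 0.24 without control replicate 1 and 0.25 without hydrogen sulfide replicate 1. Antioxidant and NRF2 target genes had a median of 0.067 (camera adjusted p = 0.0402, and adjusted p = 0.805 with an estimated correlation). The glutathione peroxidase gene GPX3 stood at 314 ± 2.95 CPM against 210 ± 5.65 CPM (SD, n = 2; log2 fold change 0.58, SE 0.15). The antioxidant list was lost without hydrogen sulfide replicate 1 (median 0.12, adjusted p = 0.140), hydrogen sulfide replicate 2 (adjusted p = 0.366) or control replicate 2, where the median was -0.0098. Its median was 0.29 without control replicate 1, and -0.017 with library totals in place of TMM. The list of thyroid, thymus and oesophagus markers, organs next to the trachea, had a median of -0.53 over 11 members (camera adjusted p = 0.0208, and adjusted p = 0.469 with an estimated correlation). Its score was -0.16 and -0.35 in the exposed libraries against 0.20 and 0.31 in the controls. The list was lost when any one of the 4 libraries was left out (adjusted p from 0.0501 to 0.128). Its median was then -0.33 and -0.25 without hydrogen sulfide replicates 1 and 2, and -0.50 and -0.34 without control replicates 1 and 2.

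The other lists did not pass with all 4 libraries. The enzymes that make or oxidise hydrogen sulfide had a median log2 fold change of 0.084 over 17 genes (camera adjusted p = 0.490), and cysteine dioxygenase CDO1 stood at 61.3 ± 4.10 CPM against 40.1 ± 12.8 CPM (SD, n = 2). The median was -0.068 and 0.14 without hydrogen sulfide replicates 1 and 2, and 0.17 and 0.013 without control replicates 1 and 2, and the list passed in none of these cases. Respiratory chain complex IV, a known target of the gas, had a median of 0.0024 and a mean of -0.057 (camera adjusted p = 0.534), with COX7A2 at 13.5 ± 2.36 against 20.8 ± 2.65 CPM. Inflammatory cytokines and chemokines had a median of -0.052 and a mean of 0.19 (camera adjusted p = 0.547). Adjusted over the list alone, 1 of them, CCL20, passed, a count that was 0 without control replicate 1 and 2 without hydrogen sulfide replicate 1 or control replicate 2. NF-kappaB and Toll-like receptor genes had a median of 0.11 (camera adjusted p = 0.703), with TLR1A at 12.7 ± 1.25 against 26.2 ± 4.03 CPM. Apoptosis and necroptosis genes had a median of -0.042 (camera adjusted p = 0.621). The unfolded protein response had a median of 0.012 (camera adjusted p = 0.160). Its member DDIT4, a stress-induced inhibitor of mTOR signalling, passed when adjusted over the list alone (log2 fold change 1.19, SE 0.19), but not when any one of the 4 libraries was left out. As lists, complex IV passed as lower without hydrogen sulfide replicate 1 (median -0.26, adjusted p = 0.0380), and the unfolded protein response as higher without control replicate 2 (0.30, adjusted p = 6.42e-05). The test also turned for complex IV without hydrogen sulfide replicate 2 (0.16) and control replicate 1 (0.11), and for NF-kappaB genes without hydrogen sulfide replicate 1 (-0.15) and control replicate 1 (0.030). It turned for apoptosis genes without hydrogen sulfide replicate 2 (0.049) and control replicate 2 (-0.024), and without control replicate 1 for cytokines (0.13) and the unfolded protein response (-0.046).

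Ciliated cell markers had a median of 0.12 (camera adjusted p = 0.206), and basal and squamous epithelial markers a median of -0.050 and a mean of 0.091 (camera adjusted p = 0.547), with the basal cell factor TP63 at 46.9 ± 8.00 against 77.0 ± 11.2 CPM (SD, n = 2). Host defence peptides and lectins had a median of 0.23 and a mean of -0.15 (camera adjusted p = 0.609). Adjusted over the list alone, 1 of them, SFTPA1, passed, and the count was also 1 without each library in turn. Smooth muscle markers (median 0.021, camera adjusted p = 0.489), neural and Schwann cell markers (0.16, camera adjusted p = 0.621), xenobiotic and lipid metabolism genes (0.024, camera adjusted p = 0.115) and erythrocyte and thrombocyte markers (0.37, camera adjusted p = 0.0509) did not pass either. For interferon-stimulated genes the median and the mean were 0.29 and the test pointed lower (camera adjusted p = 0.0934). Their score was 1.11 and -1.34 in the exposed libraries and 0.062 and 0.17 in the controls. The interferon list passed as lower without hydrogen sulfide replicate 1 (median -1.26, adjusted p = 2.36e-41) and as higher without hydrogen sulfide replicate 2 (1.01, adjusted p = 7.31e-23). Other lists passed with a library left out as well. Ciliated cell markers were higher without hydrogen sulfide replicate 1 (0.40, adjusted p = 3.12e-09) and control replicate 1 (0.29, adjusted p = 0.00313) but lower without hydrogen sulfide replicate 2 (-0.27, adjusted p = 1.72e-04). Basal markers were higher without hydrogen sulfide replicate 1 (0.19, adjusted p = 0.00493) and lower without hydrogen sulfide replicate 2 (-0.43, adjusted p = 1.05e-05). Erythrocyte and thrombocyte markers passed without hydrogen sulfide replicate 1 (0.40, adjusted p = 0.00350) and control replicate 1 (0.54, adjusted p = 0.0185), with medians of 0.091 and 0.20 without the replicates 2 of the exposed and control groups. Without control replicate 1, smooth muscle markers (0.53, adjusted p = 2.43e-04) and xenobiotic genes (0.12, adjusted p = 0.0421) passed too. Without control replicate 2 the test turned for ciliated (-0.052), smooth muscle (-0.45), neural (-0.14) and host defence genes (-0.011), and without hydrogen sulfide replicate 1 for smooth muscle (-0.23) and host defence genes (-0.43).

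FOS and the interleukin 8 homologues IL8L1 and IL8L2 were named in advance because a publication on this exposure is known to discuss them. FOS, an immediate early transcription factor, stood at 332 ± 39.2 CPM against 164 ± 60.8 CPM (SD, n = 2; log2 fold change 1.02, SE 0.31; edgeR adjusted p = 0.828, DESeq2 adjusted p = 0.302). IL8L2 stood at 5.41 ± 1.19 against 2.30 ± 1.01 CPM (1.24, SE 0.45; edgeR adjusted p = 0.869) and IL8L1 at 2.40 ± 0.251 against 1.82 ± 0.101 CPM (0.40, SE 0.36; edgeR adjusted p = 0.999). None of them passed.

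Of the 32 tested lists, 18 passed by camera with the preset correlation, 12 higher and 6 lower, against 0 with an estimated correlation and 0 by fry. With an estimated correlation camera also called the shifted list of the simulation in 0 of 10 draws. When the same 4 libraries were divided in another way, by replicate number or by W-linked reads, 9 of the 18 lists also passed, among them those of antigen presentation and T cells. The B cell, cell cycle, macrophage, mucous, ion transport and heat shock lists passed in neither of these divisions.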

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

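The W-linked term and thinning to equal depth were added after the data had been seen. The count of 0 genes by edgeR was the same under every normalization, filter, left-out library and added term in edgeR. It differed with DESeq2 (132 genes, 50 higher and 82 lower), DESeq2 with W-linked reads as a term (38, 17 higher and 21 lower) and the edgeR exact test (79, 30 higher and 49 lower). The cause was not tested. The 18 lists became 0 with an estimated correlation and 0 with fry, and otherwise ranged from 14 to 19. The B cell, cell cycle, antigen presentation, T cell, macrophage, mucous, ion transport and heat shock lists kept their direction and passed in all 14 settings other than those 2. With a library left out, the T cell median still ranged from -0.70 to -0.13, the mucous one from 0.22 to 0.57, the antigen presentation one from -1.31 to -0.51 and the macrophage one from -0.65 to -0.33. Adjusted over the list alone, the 37 cell cycle genes became 12 against a fold of 1.5 and 19 by DESeq2 with W-linked reads as a term, and ranged from 0 to 25 with a library left out. The 15 B cell markers became 9 against a fold of 1.5 and ranged from 0 to 16. A single library left in a group gives fewer degrees of freedom for the spread.

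Deviations of same-numbered libraries from their group means correlated at -0.00197 across genes, so no pairing by replicate number shows over all genes together. That correlation cannot exclude pairing or a batch in some genes. Divided by replicate number, the libraries gave 249 DESeq2 calls and 14 lists by camera with the preset correlation. The skeletal muscle score was 1.04 (exposed) and 0.76 (control) in the replicates 1, and -0.34 and -1.46 in the replicates 2. With the replicate block, 0 genes passed, 18 lists passed, and 35 cell cycle genes and 13 B cell markers passed over the list alone. Of the 18 lists, antioxidant genes no longer passed (adjusted p = 0.0587) and erythrocyte markers now did (adjusted p = 0.0342).

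With each library left out in turn, 15 lists changed the direction of their test in at least 1 case, and the cause was not tested. Their median log2 fold changes ranged from -0.15 to 0.12 for NF-kappaB genes, from -0.0098 to 0.29 for antioxidant genes, from -0.092 to 0.049 for apoptosis genes, from -0.43 to 0.19 for basal cell markers and from -0.28 to 1.62 for cartilage markers. The range was -0.27 to 0.40 for ciliated cells, -0.43 to 0.39 for host defence genes, -0.23 to 0.90 for immediate early genes, 0.075 to 0.13 for inflammatory cytokines and -1.26 to 1.01 for interferon-stimulated genes. It was -0.26 to 0.16 for complex IV, -0.14 to 0.23 for neural markers, -0.37 to 2.09 for skeletal muscle, -0.45 to 0.53 for smooth muscle and -0.046 to 0.30 for the unfolded protein response. Of the genes named in the text, RSAD2, IFIT5, NEDD4L and SKA1 changed sign. The reference table places NEDD4L and SKA1 on W, but both had reads in the libraries with few W-linked reads. With a library left out, RSAD2 ranged from -2.16 to 3.27 and IFIT5 from -2.66 to 2.16, both lowest without hydrogen sulfide replicate 1, against log2 fold changes of 2.31 and 1.21 with all 4 libraries. NEDD4L ranged from -0.335 to 0.454 and SKA1 from -0.823 to 1.06, lowest without hydrogen sulfide replicate 2 and replicate 1. NEDD4L was also lower without control replicate 2 (-0.152). IFIT5 also turned to -0.247 by limma-voom, -0.242 with the replicate block, -0.244 with W-linked reads as a term and -0.239 by DESeq2 with that term. No other gene named in the text changed sign under an alternative that tested it.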

Other observations

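Immunoglobulin transcripts (IGLL1, IGJ and the VH26L genes, 8 genes chosen after their values were seen) made up 0.246% and 0.197% of all counts in the exposed libraries and 1.43% and 1.18% in the controls. The protease inhibitor gene SPINK5 stood at 921 and 1084 CPM in the exposed libraries against 374 and 394 CPM in the controls (log2 fold change 1.38, SE 0.21; DESeq2 adjusted p = 3.97e-05, edgeR adjusted p = 0.571). SELE, an adhesion molecule of activated endothelium, stood at 58.5 and 135 CPM against 27.7 and 29.1 CPM (1.77, SE 0.42; DESeq2 adjusted p = 0.0215, edgeR adjusted p = 0.755). Among interferon-stimulated genes, RSAD2 stood at 1206 and 27.8 CPM in hydrogen sulfide replicates 1 and 2 and at 109 and 141 CPM in the controls, and IFIT5 at 1112 and 39.2 CPM against 254 and 243 CPM. The exposed libraries thus lay on either side of both controls for these genes.

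In this part, the tests of depth, of dilution by other tissue, of sex, of mixed sexes, of epithelium and of other divisions of the libraries were chosen after the results were seen. That of glucocorticoid-responsive genes was chosen after FKBP5, ZBTB16 and DDIT4 had been seen, with its list written before the values of that list were. Division of the 4 libraries into 2 and 2 can be done in 3 ways, too few to weigh chance. The main test, by edgeR, called 0 genes for exposure, 2 by replicate number and 17 by W-linked reads, of which 11 lie on the W or Z chromosome. DESeq2 called 132 genes for exposure, 249 by replicate number and 70 by W-linked reads, so 2 of the 3 divisions gave at least 132. Camera called 18 lists for exposure and at most 14 for another division, so 1 of the 3 gave as many.

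The lower B cell, plasma cell and cell cycle genes were set against 3 explanations. A difference in depth acts on a gene by its abundance. In 1000 draws of genes as abundant as the members (each from the 100 nearest), the lowest median log2 fold change was -0.195 for the B cell list and -0.146 for the cell cycle list, against -0.94 and -0.93 for the lists themselves. Moreover, 16 of the 22 and 38 of the 40 members had fewer reads in both of the deeper, exposed libraries than in either control. Both argue against depth. Muscle and cartilage scores were higher in the exposed group by 0.70 and 0.59, with larger gaps between the controls (2.21 and 1.72). Such tissue would dilute epithelial markers as well. The mean of the ciliated and basal scores minus the B cell score was 0.180 and 0.890 in the exposed libraries and -0.275 and -0.795 in the controls, a difference of 1.07 against a largest gap of 0.710 within a group. Minus the cell cycle score, it was 0.0559 and 0.935 in the exposed libraries and -0.396 and -0.595 in the controls. That difference was 0.991 against a gap of 0.879. In both contrasts hydrogen sulfide replicate 2 lay further from the controls than replicate 1. With that limit, the contrasts argue against dilution by muscle or cartilage as the whole cause. The sex of the birds is argued against by W-linked reads, which mark 1 library of each group. Libraries with and without them differed by 0.138 in the B cell score and 0.0615 in the cell cycle score, against 1.02 and 0.936 between the groups. A loss of B lineage and dividing cells under hydrogen sulfide stays a hypothesis. How much lymphoid tissue each piece of trachea held was not tested and cannot be read from whole-tissue counts. Other differences between the 2 groups' chambers cannot be told apart from the gas either.

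The higher mucous cell genes were set against more epithelium in the exposed pieces. The mucous score minus the mean of the ciliated and basal scores differed between the groups by 0.541, less than the largest gap between libraries of a group (1.13), with 0.836 and -0.295 in the exposed libraries and -0.394 and -0.147 in the controls. In hydrogen sulfide replicate 1 the ciliated and basal scores were -0.27 and -0.41, below both controls. More epithelium would thus not by itself account for its mucous score of 0.49. In hydrogen sulfide replicate 2 they were 0.37 and 0.43, above both controls, with a mucous score of 0.10. For the group, more epithelium and a change within it cannot be told apart here, because the exposed libraries differed from each other by more than the groups. In 1000 draws of genes as abundant as the mucous markers, the highest median log2 fold change was 0.226, against 0.45 for the list, which argues against depth.

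The reference table places 17 genes with at least 100 reads on the W chromosome, which hens carry and cocks lack. Of these, 14 were singled out because their reads followed an on and off pattern, with sums of 8421 in hydrogen sulfide replicate 1 and 6613 in control replicate 2, and of 10 and 0 in hydrogen sulfide replicate 2 and control replicate 1. The other 3, MBD2, NEDD4L and SKA1, had reads in all 4 libraries (NEDD4L 1799 and 3176 in the exposed, 2299 and 1438 in the controls), and why was not tested. Genes on the Z chromosome were lower in the libraries with W-linked reads, with a median log2 difference of -0.56 over 629 genes. In the median over all 17 W genes, the CPM in either library with few W-linked reads was at most 0.0983% of the mean of the others, which argues against a mix of sexes in those 2 libraries. Whether the other 2 libraries hold hens alone was not tested. The values are consistent with hens in 1 library of each group and cocks in the other library, which would balance sex between the groups. They also argue against the same birds in both libraries of a group. The labels give no sex.

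FKBP5, ZBTB16 and DDIT4, which respond to glucocorticoids in many tissues, had log2 fold changes of 1.29 (SE 0.28), 1.47 (SE 0.19) and 1.19 (SE 0.19). The DESeq2 adjusted p was 0.0497, 4.66e-04 and 0.00850, whereas the edgeR adjusted p was 0.727, 0.571 and 0.571. A candidate explanation is a stress hormone response in the exposed birds. In a list of other glucocorticoid-responsive genes written before the test, the 18 tested genes had a median of 0.21, 12 of them higher, and limma's camera gave p = 9.07e-04 with the preset correlation but p = 0.0803 with an estimated correlation. The score was 0.11 and 0.22 in the exposed libraries and -0.24 and -0.090 in the controls. The hypothesis was formed and tested on the same 4 libraries, and no hormone was measured in the data used here.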
